A study of Mus musculus with 31 samples.

How the data were processed

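The samples were 31 single neurons from acute brainstem slices of mice in which a Cre driver at the choline acetyltransferase gene (Chat) switches on the red protein tdTomato in cholinergic cells. The mouse line comes from the description of the series, whereas the labels give the genotype as wild-type. Per the deposited description of the series, red neurons were recorded by patch clamp, the cytoplasm was drawn into the pipette, cDNA was made by Smart-seq2 (full-length cDNA of polyadenylated RNA, amplified by PCR), and libraries were made with the Nextera kit, which keeps no strand, and read on a MiSeq in pairs of 75 bp. The 18 neurons of the lateral superior olive are the lateral olivocochlear (LOC) group and the 13 of the ventral nucleus of the trapezoid body are the medial olivocochlear (MOC) group, by the cell type named in each label. Groups and numbers of cells were taken from the labels alone.

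The authors deposited a table of raw read counts per gene, 1 column per cell. It held 55440 rows, of which 55421 carried mouse Ensembl identifiers and 19 were added sequences such as transgenes. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.2, DESeq2, edgeR and limma, and the builds GRCm38 and mm10. The notes give these names without their roles, and the counting tool, the handling of reads that fit several genes and the annotation release are not given in the sources used here. Reads of near-identical genes may have been split or dropped, and reads of overlapping genes on opposite strands cannot be told apart in libraries without strand. The authors also deposited a table of normalized signal values for 20784 genes, made by them as CPM on TMM-adjusted library sizes per the file's own name. Within each column every value was the raw count times 1 constant, and the columns summed to between 721736 and 1737008. The filter behind that table is not given in the sources used here, and the table served as an alternative scaling only. Gene symbols came from the GENCODE M21 annotation of GRCm38, which matched 55154 of the 55421 identifiers, and coordinates were taken from it and are counted from 1.

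From the raw counts, counts per 1000000 (CPM) were computed with the total over all mouse genes as the library size. The total per cell ran from 356412 to 2627174 counts, so that 3 counts, taken as the limit that a count of 0 allows, correspond to between 1.14 and 8.42 CPM in a single cell. A gene counted as measured with a read in at least 25% of the cells of 1 group, which held for 17754 of the 37546 genes with any read. For each gene the counts of a group were summed and given as CPM with an exact 95% Poisson interval. The share of cells with a read was given with an exact 95% Clopper-Pearson interval, and the mean and SD over cells were taken of log2(CPM + 1). Differences are LOC minus MOC of these means. They are on the log2(CPM + 1) scale, which understates the difference of low genes. Smart-seq2 reads carry no molecular identifiers, so the intervals cover counting error only and are narrower than the uncertainty about the molecules in the cell. The SD describes the spread between cells.

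Each library is 1 cell and the labels name no animal, so cells cannot be assigned to independent animals and each group counts as 1 sample. No test was run, no p-value or standard error was made from cells, and every comparison describes these libraries. edgeR 4.0.16 (R 4.3.3) served only to compute TMM sizes. A gene met the size rule for a group when its summed CPM was at least 2 times that of the other group, with 3 counts over the group as the lowest value, its mean log2(CPM + 1) was higher by at least 1, and at least 25% of that group's cells held a read.

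The 34 gene lists and the rule for named genes were fixed before the data were examined, together with most of the alternatives. The rule took 11 genes chosen from knowledge of the olivocochlear system, the 12 genes per direction with the widest mean log2 difference and a read in at least 50% of the higher group's cells, and up to 4 genes per list that met the size rule. This gave 114 genes, some of which are not reported here. A list was described by the median difference of its measured members and by the percentile of that median among 10000 random lists of the same size, matched on decile of mean expression. Below percentile 2.5 or above 97.5 the median is said to lie outside the range of random lists. This percentile describes the libraries and is no test of the cell types. Random members were drawn independently of each other, so the range takes no account of list members that vary together across cells. For lists of such genes it may be too narrow. Lists for oligodendrocytes, astrocytes, microglia, blood vessel cells, inhibitory olivary neurons and brainstem motor neurons served as markers of other cells that the pipette could pick up.

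The alternatives fixed at that point were summed counts in place of cell means, a pseudocount of 10, TMM sizes, the authors' deposited values, totals without mitochondrially encoded genes, no filter or a filter at 50% of cells, thinning of each cell to 100000 counts, removal of the 3 libraries highest in oligodendrocyte and astrocyte markers, medians over cells, and removal of each cell in turn. Added after seeing the data were the removal of the 3 libraries highest in microglial markers, the removal of libraries with more than 10% of counts on oligodendrocyte markers, and the restriction to libraries with at least 10 or at least 50 reads over Chat, Slc18a3 and Slc5a7. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

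The procedure was tested on simulated data drawn from the means, spreads and library sizes of these cells, with 200 genes of at least 50 CPM changed 4-fold. Among the 3659 genes at that level in the simulated LOC and MOC comparison, the size rule recovered 85.0% of the genes raised in LOC and 89.0% of those raised in MOC, and the median ratio of all genes raised in LOC was 3.80. It also took 8.21% of the unchanged genes, so a gene that meets the rule in isolation can do so by the spread between cells.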

Results

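Lateral and medial olivocochlear neurons are the cholinergic cells of the brainstem that send axons to the cochlea. LOC neurons end mainly on the fibres of the auditory nerve under the inner hair cells, and MOC neurons on the outer hair cells. The comparison asks which transcripts differ between the cell bodies of these 2 groups after patch-clamp recording. There were 18 LOC and 13 MOC libraries of 1 cell each and 27894270 counts in all. The total per LOC library was 792100 ± 252420 counts (mean ± SD, n = 18 cells, range 356412 to 1404896). That per MOC library was 1048959 ± 535576 counts (n = 13 cells, range 598028 to 2627174). A median of 11481 genes had a read in LOC cells (range 6654 to 18414) and 13083 in MOC cells (8572 to 19231). No pair of libraries held identical values, and the highest correlation of log2 values between any pair, across genes, was 0.82. The median correlation was 0.53 within LOC, 0.46 within MOC and 0.52 between the groups. By this measure MOC libraries were less alike than libraries of different groups. The labels name no animal, so each group is 1 sample without replicates. The SDs below are spreads between cells of 1 group, and no difference was tested. Of the 17754 measured genes, 1078 met the size rule in LOC and 1007 in MOC. The counts of list members given below are to be read against this share, which many of them do not clearly exceed. In the simulated data the rule also took 8.21% of the unchanged genes of at least 50 CPM. Many of the 1078 and 1007 genes can therefore meet it by the spread between cells. That rate covers no gene below 50 CPM.

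Genes of peptide signalling were among those with the widest differences, and Ucn, Calca, Npy and Calcb were higher in LOC cells. Ucn, which encodes urocortin, a peptide of the corticotropin-releasing factor family, had 464 CPM in the summed LOC counts (95% Poisson interval 453 to 475) and 0.66 CPM in the summed MOC counts (0.30 to 1.25). Its mean log2(CPM + 1) was 5.41 ± 3.93 in LOC and 0.51 ± 0.90 in MOC. Reads of Ucn were found in 14 of 18 LOC cells (77.8%, exact 95% interval 52.4 to 93.6) and in 4 of 13 MOC cells (30.8%, 9.1 to 61.4). Calca, the gene of calcitonin and of the vasodilator peptide CGRP, lies on chromosome 7 at 114631478 to 114636357 (minus strand, GRCm38, ENSMUSG00000030669). It reached 5687 CPM in LOC (5648 to 5727) and 213 CPM in MOC (206 to 221), and the difference of means was 3.69. Reads of Calca were present in 15 of 18 LOC and 10 of 13 MOC cells, and at least 5 reads in 12 of 18 LOC and 6 of 13 MOC cells. Npy, the gene of neuropeptide Y, had 156 CPM in LOC and 34.2 CPM in MOC (difference 2.29), with 75.8% of the MOC counts in MOC cell 4. Calcb, a close paralog of Calca whose reads the counting could have shared with it, had 178 CPM in LOC and 9.53 CPM in MOC, and 98.5% of the MOC counts came from MOC cell 10. Reads of Calcb were in 7 of 18 LOC and 3 of 13 MOC cells, and its medians over cells did not differ.

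Of the 25 measured members of the neuropeptide list, 6 met the size rule in LOC and 1 in MOC. Besides Ucn, Calca, Npy and Calcb, the LOC members were Igf1, the gene of insulin-like growth factor 1, at 56.7 against 22.2 CPM (7.70 without MOC cell 10, which held 67.7% of the MOC counts), and Pdyn, the gene of the opioid precursor prodynorphin, at 223 against 2.57 CPM. The MOC member was Pnoc, the gene of prepronociceptin, at 1.26 CPM in LOC and 87.1 in MOC. Pdyn and Pnoc fall outside the naming rule and were picked after their values were seen. A single cell gave 63.4% of the LOC counts of Pdyn and 86.2% of the MOC counts of Pnoc. Penk, the gene of proenkephalin, did not meet the rule and stood at 36.3 CPM in LOC and 58.4 CPM in MOC, with a mean difference of -0.75. This difference was -0.30 without MOC cell 2, -0.48 without MOC cell 9 and -0.50 without MOC cell 1. The median difference of the list was 0.12, at percentile 92.3 of random lists, so the list as a whole was inside their range. The median was -0.07 with the authors' normalized values, and 0.73 at percentile 99.8 with summed counts. In libraries with at least 10 reads over Chat, Slc18a3 and Slc5a7, a restriction chosen after seeing the data, it was -0.18 at percentile 27.2.

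The list of genes that process and release peptides was higher in LOC by its median, although most members did not meet the size rule. The 16 measured members of the list of peptide processing and dense-core vesicles had a median difference of 0.67, at percentile 99.7 of random lists, and 14 members lay above 0. The size rule was met by 4 members in LOC and 0 in MOC. Pcsk1, which encodes the prohormone convertase that cuts peptide precursors, had 98.6 CPM in LOC (93.5 to 103.9) and 2.64 CPM in MOC (1.85 to 3.65). Baiap3, a protein of dense-core vesicle recycling, had 84.8 and 1.98 CPM. Tsr3 overlaps Baiap3 on the other strand. Pam, the enzyme that amidates peptide ends, had 248 and 81.0 CPM, and Resp18, a protein of dense-core granules, 409 and 165 CPM. The reads of Pam and of B230216N24Rik, a transcript inside it on the same strand, cannot be told apart with certainty. Without MOC cell 13 the difference of Resp18 was 0.82 in place of 1.30. Without MOC cell 2 the list median was 0.41, at percentile 97.3 and inside the range of random lists.

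**Figure D1:**
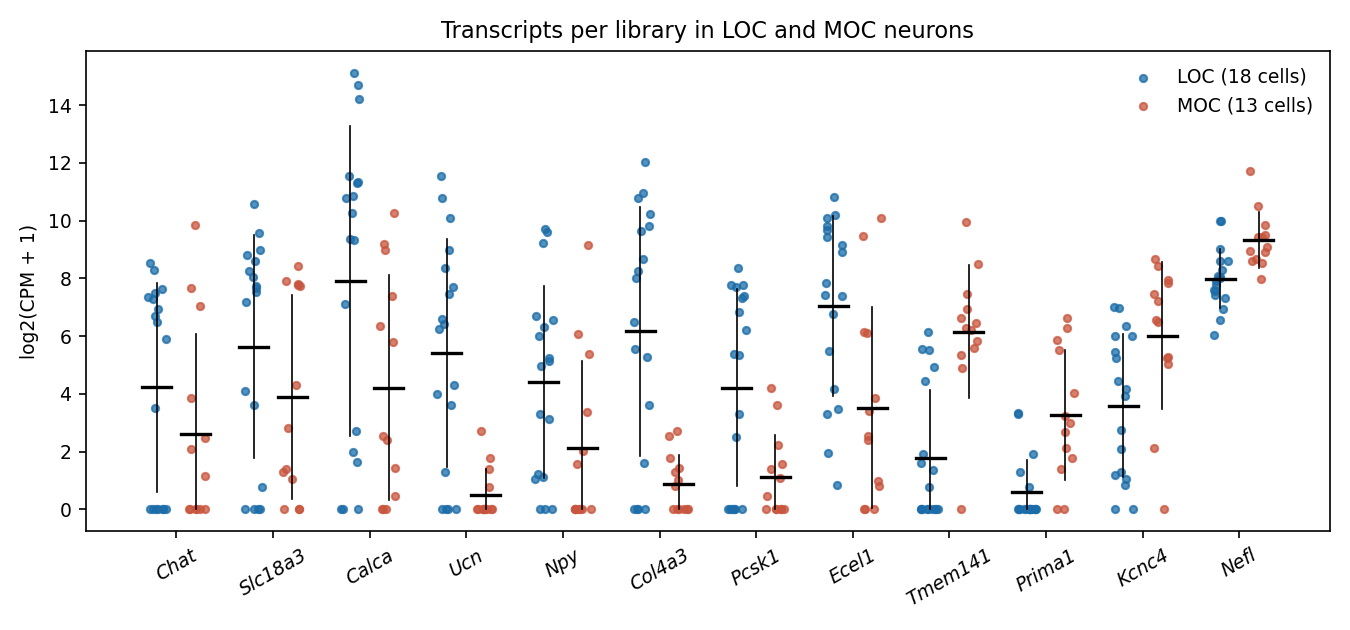
Values of log2(CPM + 1) for 12 transcripts in each of the 18 LOC (blue) and 13 MOC (red) libraries, 1 point per cell, with the mean as a thick black bar and 1 SD between cells to each side, ended at 0, as a thin line. LOC points of Ucn and Col4a3 spread from 0 to over 10, with means of 5.41 and 6.16, whereas the MOC means were 0.51 and 0.89.

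Outside the peptide lists, the genes with the widest difference toward LOC were led by Col4a3. This gene of the collagen IV alpha 3 chain (chromosome 1, 82586921 to 82722059, plus strand) had 707 CPM in LOC (693 to 721) and 1.10 CPM in MOC (0.62 to 1.81), with means of 6.16 ± 4.31 and 0.89 ± 1.003. Its head-to-head neighbour Col4a4 had 269 and 5.28 CPM. Col4a2 had 261 and 12.1 CPM, and Col4a1, which overlaps the start of Col4a2 on the other strand, 91.0 and 6.16 CPM. These chains build the collagen network of basement membranes. Cpne7, a calcium-dependent phospholipid-binding copine, had 437 CPM in LOC and 0.81 CPM in MOC (difference 5.22). Syt5, a synaptotagmin, had 114 and 3.74 CPM (difference 4.24), with 64.7% of the MOC counts in MOC cell 13. The rest of the widest differences were in Prmt2, an arginine methyltransferase (294 and 12.8 CPM), Cidea, a lipid droplet protein (150 and 7.92 CPM), Anxa2, the gene of annexin A2 (538 and 27.4 CPM), B230216N24Rik (124 and 1.17 CPM) and Bmp3, a bone morphogenetic protein (147 and 8.14 CPM). A single library gave 96.4% of the MOC counts of Bmp3 and 86.1% of those of Cidea.

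The widest difference toward MOC was that of Tmem141, which encodes a small membrane protein (chromosome 2, 25620067 to 25622005, minus strand). It had 11.2 CPM in LOC (9.55 to 13.1) and 136 CPM in MOC (129 to 142), with means of 1.79 ± 2.35 and 6.16 ± 2.29. Reads of it were present in 9 of 18 LOC and 12 of 13 MOC cells. Cryl1, the gene of a lambda crystallin, had 2.52 CPM in LOC and 99.0 CPM in MOC. Coro7, a coronin, had 19.2 and 102 CPM and overlaps 2 genes on the other strand, Vasn and Dnaja3. Ckmt1, the gene of a mitochondrial creatine kinase, had 125 and 482 CPM and was read in all 31 cells. Agtr2, the type 2 angiotensin receptor, had 0.56 CPM in LOC and 107 CPM in MOC, 57.6% of the MOC counts in a single cell. Socs3, Mrpl35, Galnt9, Vstm2a, Cdh22, Hs3st5 and Wdr41 completed the 12, with mean differences between -2.96 and -2.75.

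Transcripts that define cholinergic neurons were present in both groups. Slc18a3, the gene of the vesicular acetylcholine transporter, had 299 CPM in LOC (290 to 308) and 88.2 CPM in MOC (83.3 to 93.3), with a mean difference of 1.75 and reads in 14 of 18 and 10 of 13 cells. Chat had 100 and 68.6 CPM (29.3 without MOC cell 5) and reads in 11 of 18 and 7 of 13 cells. Its mean difference was 1.61, but its ratio of 1.46 was below the size rule. Slc18a3 lies within Chat on the same strand, so their reads may be shared. Slc5a7, the choline transporter, had 129 and 77.2 CPM, and its mean difference of 0.44 ranged from 0.11 without MOC cell 4, 8 or 13 to 0.86 without MOC cell 5. It was 1.48 after thinning to 100000 counts and -0.25 without the 3 libraries highest in microglial markers. Isl1, a transcription factor of motor neurons, had 55.5 and 68.7 CPM, and Gata3, a factor needed for olivocochlear neurons, 132 and 54.4 CPM. Neither met the rule. Without MOC cell 2 the mean difference of Isl1 went from 0.82 to 1.37, without MOC cell 10 to 1.29 and without LOC cell 15 to 0.53. That of Gata3 went from 0.70 to 1.08 without MOC cell 4, to 0.44 without MOC cell 7 and to 0.45 without MOC cell 13. With summed counts the difference of Isl1 was -0.30, and without the 3 libraries highest in microglial markers that of Gata3 was -0.12. In the list of 14 cholinergic markers, 3 members were higher in LOC, namely Ecel1 (511 and 96.5 CPM), Gata2 (126 and 21.1 CPM) and Slc18a3. The member higher in MOC was Prima1, which anchors acetylcholinesterase to the membrane, at 1.12 and 22.9 CPM. MOC cell 4 gave 51.9% of the MOC counts of Ecel1, which came to 48.6 CPM without it. The list median of 0.57 lay at percentile 98.5 of random lists. It lay inside the range with summed counts (0.54, percentile 97.3) and with a pseudocount of 10 (0.26, percentile 95.9). With choices made after seeing the data it was -0.02, at percentile 38.0, without the 3 libraries highest in microglial markers, and 0.71, at percentile 92.4, without libraries above 10% oligodendrocyte markers. The 3 libraries highest in microglial markers, MOC cells 7, 8 and 12, held 28, 0 and 9 reads over Chat, Slc18a3 and Slc5a7. The list median was also inside the range without LOC cell 3, 4, 5, 8, 11, 13, 15 or 18 or MOC cell 7, 8, 11, 12 or 13, with the lowest value of 0.34 without MOC cell 8.

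The libraries differed in how many cholinergic reads they held. In 4 LOC and 5 MOC libraries there were fewer than 10 reads over Chat, Slc18a3 and Slc5a7 together, with 0 in LOC cells 14 and 16 and MOC cell 8. MOC cell 8 held 1690 CPM of Gad1, the GABA-synthesizing enzyme, and 817 CPM of Slc6a5, the glycine transporter of glycinergic terminals. Reads of the tdTomato sequence were found in 11 LOC and 9 MOC cells. In libraries with at least 10 of these cholinergic reads (14 LOC and 8 MOC), the difference of Ucn was 6.36, of Calca 3.74 and of Tmem141 -4.19. With at least 50 (12 LOC and 5 MOC) these differences were 7.71, 4.45 and -3.88. Both restrictions were chosen after seeing the data.

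**Figure D2:**
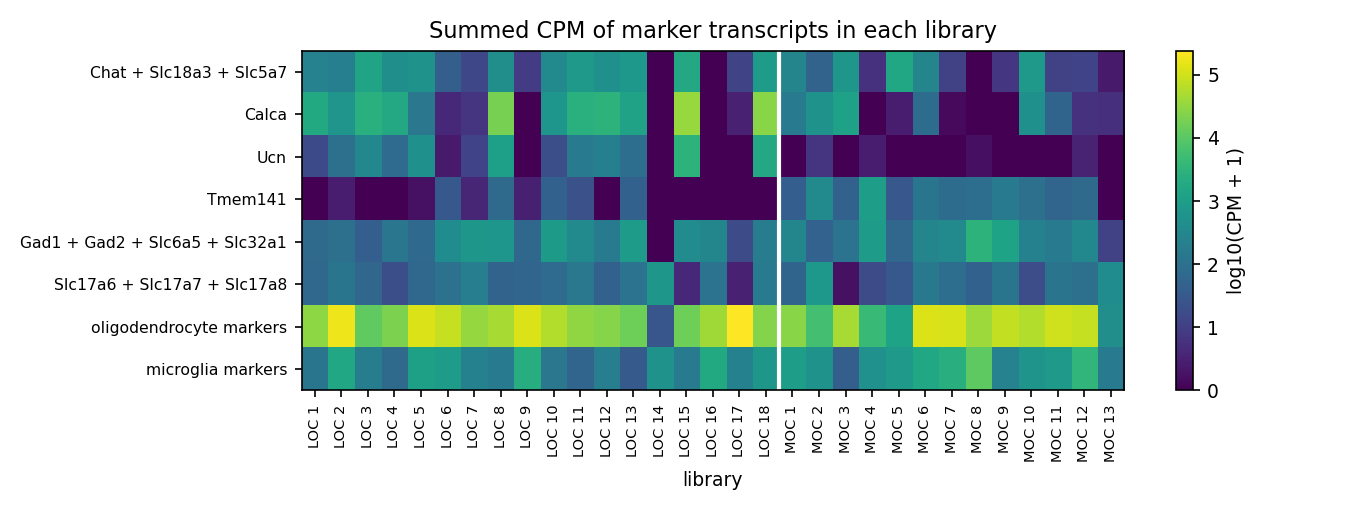
Summed CPM of marker transcripts in each of the 18 LOC and 13 MOC libraries, as log10(CPM + 1) on a colour scale, with the white line between the groups. Calca and Ucn were highest in LOC cells 8, 15 and 18, and microglia markers reached 11139 CPM in MOC cell 8.

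Among genes of membrane excitability, 4 genes of the sodium channel list and 4 of the calcium channel list met the size rule in LOC, and 2 Kv3 genes, 1 Kv1 gene and a Kv1 partner met it in MOC. The medians of these lists lay inside the range of random lists. Some of the genes fell under the rule's difference of 1 in an alternative. Cacna1b went from 1.14 to 0.73 with a pseudocount of 10, and Nalcn from 1.88 to 0.96 in libraries with 50 or more cholinergic reads. Of the 21 measured genes for sodium channels, HCN channels and the leak channel NALCN, 4 met the rule in LOC and 0 in MOC. Scn9a, the gene of Nav1.7, had 79.7 CPM in LOC and 5.21 CPM in MOC, Scn3a 99.5 and 13.6 CPM, Scn2a 132 and 42.1 CPM and Nalcn 68.6 and 20.4 CPM. The median of this list was nevertheless -0.16 (percentile 18.4), because 12 members lay below 0. Of the 27 measured calcium and TRP channel genes, 4 met the rule in LOC and 0 in MOC (median 0.29, percentile 93.2). They were the L-type channel gene Cacna1c (42.0 and 6.45 CPM), the T-type gene Cacna1g (76.2 and 32.6 CPM), Cacnb2 and the N-type gene Cacna1b. Among 26 genes of Kv1, Kv2 and Kv3 channels and their partners, 0 met the rule in LOC and 4 in MOC (median -0.17, percentile 18.7). Kcnc4, which encodes Kv3.4, had 30.1 and 147 CPM, Kcna1, which encodes Kv1.1, 94.6 and 206 CPM, and Kcnc2, which encodes Kv3.2, 6.17 and 19.1 CPM. Lgi3, a secreted partner of Kv1 complexes, had 76.5 and 304 CPM. Of 9 genes for Kv4 channels and their subunits, Kcnip4 alone met the rule, in MOC (33.5 and 92.6 CPM, list median 0.22, percentile 73.9). Of 33 other potassium channel genes 1 met the rule, Kcnt2 in LOC (median 0.02, percentile 65.3). LOC cell 2 gave 68.6% of its LOC counts, and its difference of 0.65 without that cell no longer met the rule.

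Receptor genes went in both directions. Of 22 genes for AMPA and kainate receptors and their partners, 2 met the rule in LOC and 1 in MOC (median 0.02, percentile 56.0). Gria1, the GluA1 subunit, had 249 and 93.6 CPM and its partner Cnih2 177 and 36.0 CPM, while Cacng3 had 16.4 CPM in LOC, 84.6% of it in a single cell, and 35.2 CPM in MOC. Grm5, the metabotropic receptor mGluR5, had 99.9 and 19.6 CPM and was the single member of its list of 11 to meet the rule (median 0.47, percentile 94.6). No member of the NMDA receptor list met it (7 genes, median -0.24, percentile 25.8). Of 20 GABA receptor genes 1 met the rule in LOC and 2 in MOC (median -0.26, percentile 10). Gabra2, the alpha 2 subunit, had 47.6 CPM in LOC and 6.45 CPM in MOC, and Gabrb2, the beta 2 subunit, 9.89 and 49.1 CPM. For Gabrb2, MOC cell 8 gave 59.4% of the MOC counts, which came to 22.3 CPM without it, and LOC cell 14 gave 50.4% of the LOC counts. The other MOC member was Gabrg3, with 54.5% of its MOC counts in MOC cell 13. Its difference of -0.81 without that cell no longer met the rule. In the list of 9 genes for glycine receptors and chloride transporters, Gphn, the gene of the scaffold protein gephyrin (41.2 and 85.9 CPM), and Glra1, the alpha 1 glycine receptor (16.6 and 35.8 CPM), met the rule in MOC (median -0.34, percentile 10.7). This list lay outside the range in 4 of 14 alternatives, at -1.04 and percentile 0.28 with summed counts, and had a median above 0 in 2 others. Of 18 genes for acetylcholine receptors and their partners, 2 met the rule in LOC, the receptor gene Chrnb2 (148 and 49.9 CPM) and the partner gene Ly6h. In MOC 3 met it, among them Chrna4 (7.36 and 31.6 CPM) and Chrna2, which was read in 4 of 13 MOC cells (list median 0.02, percentile 70.2).

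Among the channel and receptor genes named and the oxidative phosphorylation genes, several overlap another gene on the opposite strand, so their reads may be shared. This holds among others for Scn9a with Gm13629, Cacna1c with Dcp1b, Kcnip4 with 5730480H06Rik, Cnih2 with Yif1a, Chrnb2 with Adar and Ndufs1 with Eef1b2.

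Of 33 genes in the list of peptide, opioid, purine and endocannabinoid receptors, 4 met the rule in LOC and 1 in MOC (median 0.02, percentile 80.1). Hcrtr2, the orexin receptor 2, had 32.3 and 2.57 CPM and reads in 11 of 18 and 3 of 13 cells, with 94.3% of the MOC counts in a single cell. Oxtr, the oxytocin receptor, had 94.1 and 1.61 CPM with reads in 10 of 18 and 9 of 13 cells, and its medians over cells differed by 0.23 against 1.92 for the means. At least 5 reads of Oxtr were present in 6 of 18 LOC and 1 of 13 MOC cells. Oprl1, the nociceptin receptor, had 223 and 74.7 CPM. Hcrtr1, the orexin receptor 1, had 55.5 and 1.47 CPM and a mean difference of 1.18, but its median over cells was lower in LOC (difference -0.47), with reads in 8 of 18 LOC and 7 of 13 MOC cells. At least 5 reads of Hcrtr1 were present in 5 of 18 LOC and 0 of 13 MOC cells. Its MOC detections and its lower LOC median therefore rest on few reads per cell. Of 26 monoamine receptor genes, Hrh1, the histamine H1 receptor, met the rule in LOC, at 91.8 CPM with 59.0% of it in a single cell, against 0.95 CPM in MOC, and 1 gene, Htr3a, met it in MOC (median -0.18, percentile 27.9). MOC cell 3 gave 64.2% of the MOC counts of Htr3a. The difference of Htr3a no longer met the rule without MOC cell 3 (-0.72) or without MOC cell 6 (-0.73).

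Single genes of large axons and of vesicle release and the list of oxidative phosphorylation genes were higher in MOC. Nefl, the light neurofilament chain, had 307 CPM in LOC (298 to 316) and 883 CPM in MOC (867 to 899), with means of 7.99 ± 1.03 and 9.32 ± 0.97 and reads in all 31 cells. Nefm had 319 and 972 CPM. The span of Nefl lies inside that of Nefm on the other strand, so their reads may be shared. In their list of 18 genes, 0 met the rule in LOC and 3 in MOC, and the median of -0.37 lay at percentile 2.6, just inside the range of random lists. The neurofilament list lay outside that range in 7 of 14 alternatives, at percentile 0.61 with summed counts, whereas with medians over cells its median was -0.02 at percentile 57.1. Cplx1, a complexin that clamps and triggers vesicle fusion, had 273 and 929 CPM (means 7.60 ± 1.45 and 9.29 ± 1.47), and Sv2c, a vesicle glycoprotein, 32.8 and 80.7 CPM. The list of 40 release genes split into 3 in LOC and 4 in MOC (median -0.09, percentile 23.7). The 28 nuclear genes of oxidative phosphorylation had a median of -0.43, at percentile 0.21, with 23 members below 0. The rule was met by 0 in LOC and 5 in MOC, among them Sdhb (155 and 368 CPM), Ndufs1 (89.8 and 191 CPM), Cycs, the gene of cytochrome c (56.7 and 136 CPM), and Uqcrc2 (84.5 and 176 CPM). The difference of Uqcrc2 turned to 0.14 without libraries above 10% oligodendrocyte markers and to 0.23 in libraries with 50 or more cholinergic reads, and that of Ndufs1 was -0.084 with medians over cells. The share of counts on mitochondrially encoded genes went the other way, with a median of 21.4% in LOC (range 2.36 to 43.7) and 11.5% in MOC (1.56 to 32.5).

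**Figure D3:**
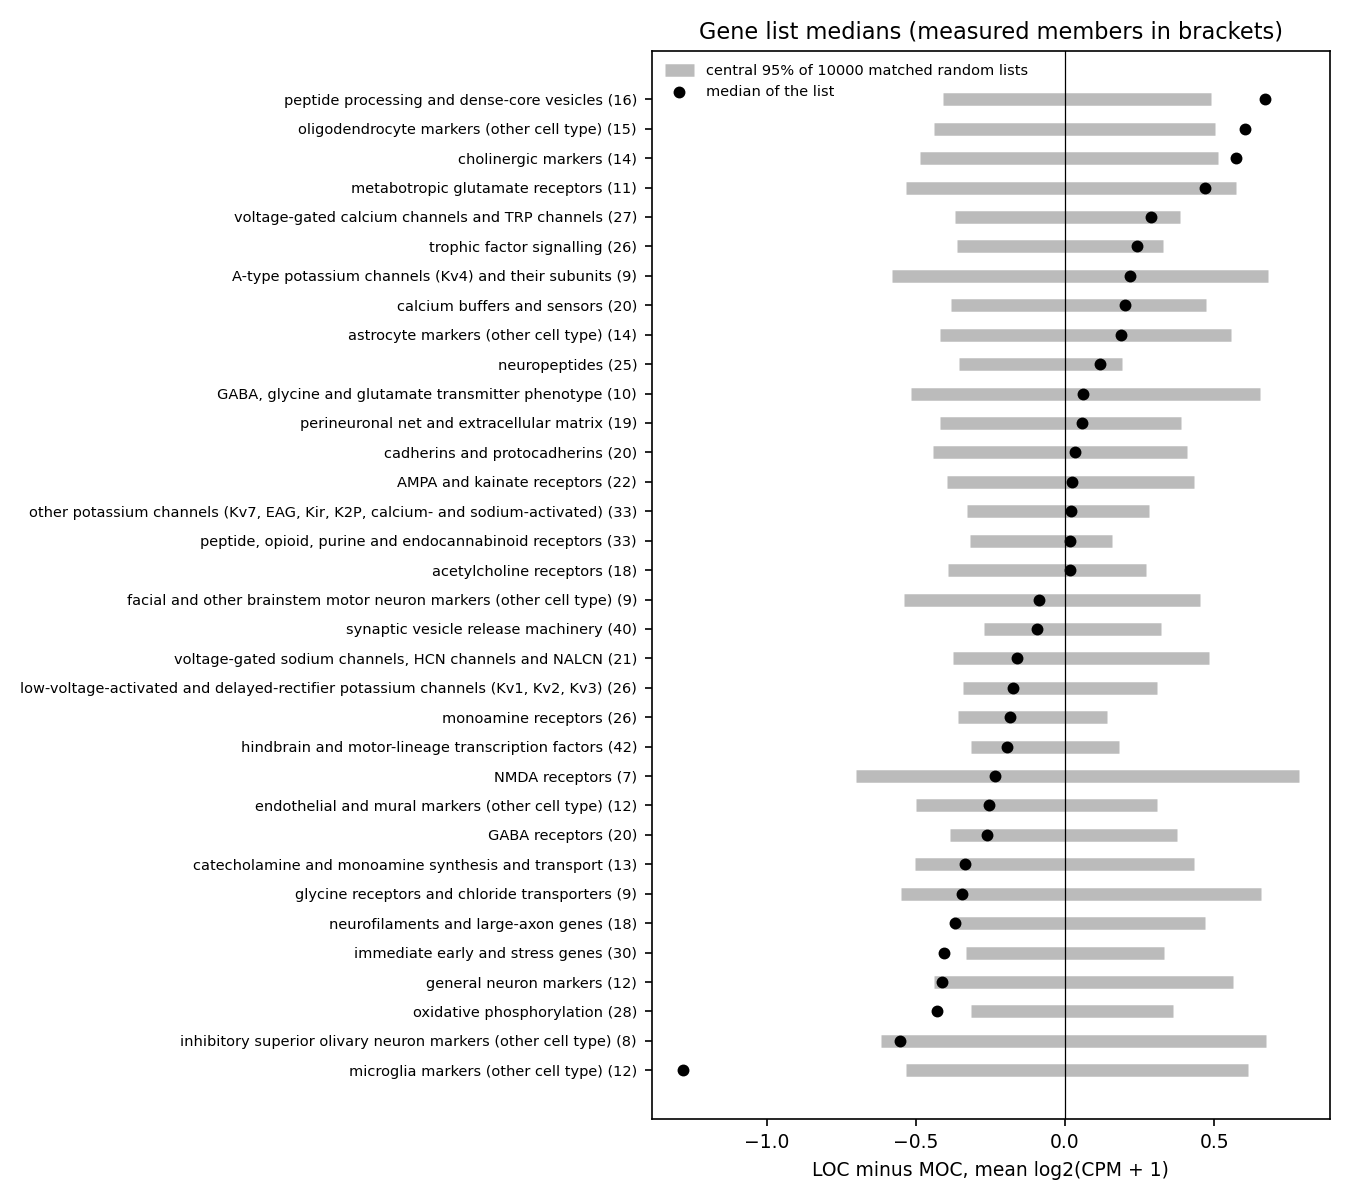
Median over the measured members of each of the 34 gene lists of the LOC minus MOC difference in mean log2(CPM + 1), as black points, with grey bars for the central 95% of 10000 random lists matched on expression. The points of peptide processing (0.67), oligodendrocyte markers (0.60), cholinergic markers (0.57), immediate early genes (-0.41), oxidative phosphorylation (-0.43) and microglia markers (-1.28) lie outside their bars.

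The lists that follow had medians inside the range of random lists. Of the 28 lists inside it, 8 left it when certain single cells were left out, in 1 to 10 of the 31 cases per list. The neurofilament list did so in 10 cases, for example at percentile 1.54 without MOC cell 11, and the general neuron markers in 6. Of 42 hindbrain and motor-lineage transcription factors, 3 met the rule in LOC, among them Gata2 and Ebf1 (38.9 and 19.0 CPM), and 4 in MOC, among them Zfhx4 (7.22 and 27.2 CPM) and Pbx3 (median -0.19, percentile 16.9). Of 20 cadherin genes 2 met the rule in LOC, Cdh12 and Celsr3, and 4 in MOC, among them Pcdh17 (27.4 and 72.6 CPM) and Cdh13 (median 0.03, percentile 62.8). Of 19 genes of the extracellular matrix, 3 collagen IV genes met it in LOC and Hapln4, a link protein of perineuronal nets, in MOC (23.0 and 68.0 CPM, list median 0.06, percentile 68.0). Of 26 genes of trophic factor signalling 4 met it in LOC, among them Igfbp5 and Ntrk3, the receptor of neurotrophin 3 (219 and 109 CPM), and 1 in MOC, Il6st (median 0.24, percentile 93.7). Of 20 calcium buffers and sensors 0 met it in LOC and 3 in MOC, among them Sncg, the gene of gamma-synuclein (39.3 and 350 CPM, list median 0.20, percentile 77.7). MOC cell 3 gave 50.8% of the MOC counts of Sncg, which came to 191 CPM without it. Of 13 genes of catecholamine and monoamine synthesis and transport, Slc6a2, the noradrenaline transporter, met it in MOC (3.65 and 29.99 CPM, list median -0.34, percentile 10.9). MOC cell 2 gave 60.6% of its MOC counts, and without that cell they came to 12.6 CPM. Th, the gene of tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, had 13.96 CPM in LOC and 40.3 CPM in MOC and did not meet the rule. Its mean difference of -0.40 became 0.05 without MOC cell 10 and 0.43 with medians over cells. Of 12 general neuron markers Nrsn1 met the rule in MOC (median -0.41, percentile 3.1).

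Of the 30 immediate early and stress genes, 2 met the rule in each direction, among them Nr4a1 in LOC (152 and 74.1 CPM) and Atf3 in MOC (45.6 and 102 CPM). The mean difference of Nr4a1 went from 1.44 to 0.029 in libraries with 10 or more cholinergic reads, and that of Atf3 from -1.24 to -0.34 without the 3 libraries highest in microglial markers. The median of -0.41 lay at percentile 0.81. It was inside the range of random lists with summed counts (-0.26, percentile 15.1), after thinning to 100000 counts (-0.35, percentile 3.23), in libraries with at least 10 (-0.14, percentile 29.7) or 50 (-0.19, percentile 22.1) cholinergic reads, and without MOC cell 5 (-0.34), 8 (-0.33) or 13 (-0.37).

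Single cells weighed on the summed CPM of many genes. For 66 of the 114 named genes, the summed CPM of LOC, MOC or both was over 1.5 times its value without the cell with the most reads. Besides the genes for which this share is given, 1 cell held over 50% of the LOC counts of Cryl1, Chrna2, Chrna4, Trem2, Cdh13, Calcb, Wdr41, Vstm2a, Mrpl35, Socs3, Cacnb2 and Agtr2. The same holds for the MOC counts of Calca, Ucn, Chat, Isl1, Penk, Ctss, Baiap3, Nrsn1, Oxtr, Hrh1, Scn3a, Scn9a, Cacnb2, Col4a4 and B230216N24Rik. Of the 108 named genes that met the size rule, 89 kept a ratio of summed CPM of at least 2 without the cell with the most reads in the higher group. The other 19 included Igf1, Nr4a1, Cacna1b, Cacna1g, Igfbp5, Ebf1 and Ntrk3 in LOC and Glra1, Gphn, Kcna1, Ndufs1, Uqcrc2, Atf3, Nrsn1, Opalin, Mrpl35 and Cacng3 in MOC.

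Transcripts of other cells were present in both groups. Oligodendrocyte markers took a median of 32695 CPM in LOC libraries (range 27.0 to 241352) and 46588 CPM in MOC libraries (461 to 125229). The list median of 15 genes was 0.60, at percentile 99.1, but it was -0.30 with summed counts and -0.40 with medians over cells, and 0.07 without MOC cell 4 or MOC cell 13. It was also inside the range of random lists without LOC cell 2, 5, 9, 16 or 17 or MOC cell 1, 2, 5 or 10. In this list 0 genes met the rule in LOC and 2 in MOC, Olig1 (67.2 and 215 CPM) and Opalin. Microglia markers took a median of 215 CPM in LOC (32.4 to 2253) and 781 CPM in MOC (40.7 to 11139). All 12 were lower in LOC by mean log2 value, 7 of them by the size rule (median -1.28, percentile 0.00), among them Ctss (47.6 and 345 CPM), Csf1r (67.1 and 257 CPM) and Trem2 (3.37 and 45.3 CPM). Without MOC cell 8 the median was -0.84, and without the 3 libraries highest in these markers, a choice made after seeing the data, it was -0.42 at percentile 5.1. Astrocyte markers had a median of 0.19 (14 genes, 1 met the rule, in MOC, percentile 71.1) and endothelial and mural markers -0.25 (12 genes, 0 met it, percentile 22.2). In the list of inhibitory olivary neurons 2 of 8 genes met the rule in MOC, Gad1 (56.0 and 307 CPM, 58.5% of the MOC counts in MOC cell 8) and Glra1 (median -0.55, percentile 3.7). The list of GABA, glycine and glutamate transmitter genes had 1 of 10 in MOC, again Gad1 (median 0.06, percentile 51.9). In the list of other brainstem motor neurons Calca was the single one of 9 measured genes to meet the rule, in LOC (median -0.09, percentile 48.8).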

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

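The count table holds sequences that are not mouse genes and that no comparison above used. With no control samples, a sequence is given here where a library held more than the 3 counts that a count of 0 allows. The sequence named DsRed exceeded this in 30 of the 31 cells, mLamp3 in 28, hspCas9 in 26 and tdTomato, the reporter of the mice, in 19. LacZ exceeded it in 14 cells, the neomycin resistance sequence in 10, CRE-ERT2 in 5 and GNAS-R201C-EE in 4. The sequences of beta-lactamase and of RVG exceeded it in 2 cells each, and AAV2 and firefly luciferase in 1 cell each. All 19 such sequences together took at most 0.052% of the counts of a library.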

How the results depend on the processing

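No paired analysis was possible because the numbers that both groups share only name cells, and the results come from no test. The 4 alternatives named as chosen after seeing the data are marked as such in the account of the processing. No cell had under 100000 counts, so that filter removed nothing and gave no values. Of 1590 values of the 114 named genes under the alternatives other than leaving out 1 cell, 1573 moved by less than 1 SD between cells, a wide bound here, 14 moved by more and 3 reversed. Leaving out 1 cell can hardly move a mean by that SD, so those values are not counted. The alternatives with no filter on detection and with one at 50% of cells leave the values of single genes as they are. Those values count among the 1573 by construction. Over all genes, 1078 met the size rule in LOC and 1007 in MOC. With a pseudocount of 10 these counts were 370 and 209, and with TMM sizes 905 and 1232. Reversals were counted only for genes that met the size rule. Of the 6 named genes that did not meet it, 4 (Isl1, Gata3, Slc5a7 and Th) changed sign in 5 values. The reversed values were those of Hcrtr1 and Uqcrc2. That of Hcrtr1, which had at least 5 reads in 0 of 13 MOC cells, was -0.465 with medians over cells. Those of Uqcrc2 were 0.142285 without libraries above 10% oligodendrocyte markers and 0.234 in libraries with 50 or more cholinergic reads. Among the 6 lists outside the range of random lists, the oligodendrocyte list reversed to -0.300 with summed counts and to -0.397 with medians over cells, and the cholinergic list to -0.0241 without the 3 libraries highest in microglial markers. Those 3 libraries, MOC cells 7, 8 and 12, held 28, 0 and 9 reads over Chat, Slc18a3 and Slc5a7. The cause was not tested for any of the reversals. The median difference over all measured genes was -0.07, and it was -0.13 with TMM sizes and 0.07 after thinning. Of the 28 lists inside the range of random lists, 22 changed sign under at least 1 alternative other than leaving out 1 cell and have no firm direction. They include the inhibitory olivary list (-0.84 to 0.25), GABA receptors (-0.35 to 0.45), NMDA receptors (-1.06 to 0.50), endothelial markers (-0.35 to 0.31) and astrocyte markers (-0.52 to 0.54). Of the 28, 12 lay outside the range under at least 1 of these alternatives. The lists of peptide processing (0.40 to 1.13) and oxidative phosphorylation (-0.83 to -0.33) stayed outside the range of random lists in 14 of 14 alternatives, microglia markers (-1.89 to -0.42) in 13 of 14, immediate early genes in 10 of 14, cholinergic markers in 8 of the 12 that apply to them, and oligodendrocyte markers in 6 of 14. Depth limits single cells, in which 3 counts correspond to as much as 8.42 CPM.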

Other observations

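All tests reported here were chosen after the results were seen. The LOC reads of Calca, Calcb, Ucn and Npy were concentrated in few cells, whereas those of Igf1 were highest in LOC cells 13 and 1 (284 and 218 CPM). LOC cells 8, 15 and 18 were the 3 highest LOC cells for Calca, Ucn and Npy alike, and included 2 of the 3 highest for Calcb. Their Calca values lay between 18871 and 35892 CPM, against at most 3027 CPM in the other LOC cells. Their Ucn values lay between 1103 and 3022 CPM, against at most 504 CPM, and their Npy values between 594 and 830 CPM, against at most 104 CPM. These 3 cells held 85.5% of the LOC reads of Calca, 83.6% of Calcb, 76.3% of Ucn and 83.2% of Npy. Outside the LOC group, the highest Npy value was 567 CPM in MOC cell 4, which held 3 cholinergic reads and no Calca read.

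Of the 31 libraries, 9 held fewer than 10 reads over Chat, Slc18a3 and Slc5a7. Shallow sequencing alone is argued against as the cause. At the total of the shallowest library, 356412 counts, only 3 of the other 22 libraries would be expected to hold fewer than 10 such reads. LOC cells 7, 9 and 16, with the lowest totals of all libraries (356412, 491782 and 507955 counts), were among the 9. So were MOC cells 8 and 9, with 1449411 and 991757 counts. A part played by depth in the shallow libraries stays open. RNA of inhibitory or glutamatergic neurons in place of the labelled cell stays open. In 2 of the 9, MOC cells 8 and 9, the summed CPM of Gad1, Gad2, Slc6a5 and Slc32a1 was above that of each of the other 22 libraries (2990 and 1342 CPM, against at most 949). Against an unlabelled cell in place of the labelled one speak reads of the tdTomato reporter in 4 of the 9, with 93 in MOC cell 8, the most of the 31 libraries, 48 in MOC cell 4, 8 in MOC cell 9 and 4 in LOC cell 14. Such reads bear on whether a red cell was sampled, not on whether it was an olivocochlear neuron or the only cell sampled. The 4 reads of LOC cell 14 lie close to the 3 counts that a count of 0 allows. The other 5 held none, which says little. LOC cells 1 and 2 had 0 tdTomato reads as well, although they held 211 and 265 cholinergic reads. For the vesicular glutamate transporters the outcome rests on MOC cell 2, which at 733 CPM was the highest of the other 22 libraries and above each of the 9. Without it the highest was 165 CPM, and LOC cells 7 and 14 and MOC cell 13 lay above that, at 196, 710 and 413 CPM. These few libraries cannot decide between a different cell, a loss of the transcripts before amplification and cells low in them. No biological explanation was tested.

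Microglia markers were higher in MOC libraries. Microglial RNA carried into the libraries may account for the reads, but the test did not decide it. With 6 of the markers used to choose the 5 highest libraries, these lay above the median of all libraries in 4 to 6 of the other 6 markers, where at least 5 in each had been set as the bound. Of these 5 libraries 3 were MOC and 2 were LOC (cells 9 and 16), so the test bears on the source of the reads and not on the difference between the groups. Microglia occur in the tissue through which the pipette passes, and no sort removed them. Whether a difference is carried by the 3 highest MOC libraries alone cannot be told apart from one of the whole group. Of the 13 MOC libraries, 11 lay above the LOC median of 215 CPM, and without those 3 libraries the list median was -0.42. A difference between the nuclei in their microglia, or in the reaction to recording, was not tested and stays open.

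Transcripts abundant in LOC appeared with single-digit reads in MOC libraries. Ucn, Col4a3 and Cpne7 together had 35 reads in the 13 MOC libraries and 22935 in LOC, or 0.153% of the LOC reads, with at most 5 reads per gene and MOC library. An even spill of reads between all libraries, as from shared index reads, would at this rate bring 5.43 to 23.8 Calca reads into each MOC library. The counts of 4 MOC libraries lay under the lower 95% Poisson bound, and 3 held no Calca read, which argues against an even spill as the whole source. The bound took the rate as exact, although it rests on 35 reads. The margin was widest in MOC cell 7, with 1 Calca read against a bound of 15. It was narrowest in MOC cell 4, with 0 against a bound of 2. Spill within sequencing runs, which the labels do not name, and low expression in MOC cells stay open.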
